A study of Mus musculus with 6 samples.

How the data were processed

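RNA was measured in tumour-associated macrophages sorted by flow cytometry from implanted CT26 tumours, a mouse colon carcinoma line that grows in BALB/c hosts. The site of implantation is not given in the sources used here. Tumours were taken on day 15 and carry the labels Sg-Con and Sg-C3, read here as tumour cells with a control guide RNA and with a guide RNA against C3. The macrophage samples are labelled wild type, so C3 RNA in the macrophages does not check those labels. There were 6 libraries, 3 per group. Replicates are named here in accession order within each group, and nothing in the labels pairs them across groups. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

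The deposited table holds 1 value per gene and library, with 2 decimals, for 15487 genes, and its column names call the values FPKM. Per the labels' protocols, RNA was extracted with Trizol, and the labels name both a TruSeq and an MGIEasy kit for library preparation. Per the submitters' processing notes, Bowtie 0.12.2 and the mm8 build were used. The tool that computed FPKM is not given in the sources used here. The table has no read counts, so tests made for counts were not run. A column that sorts the genes into clusters was not used here. Gene symbols were taken from the table, except 23 that a spreadsheet had turned into dates, which were restored from their gene identifiers with the RefSeq table of GRCm38. Of the identifiers, 15440 were found in that table. Its build differs from mm8, so no coordinates are given. The reference genome comes from another strain than BALB/c, which can lower the FPKM of polymorphic genes such as the MHC genes in both groups alike, and near-identical members of the MHC, Gbp and Klra families can share reads.

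Depth was read from the values themselves. In 423 short non-coding genes, values of up to 8 reads fell on whole multiples of 1 read once 36 bases were taken from each gene's length. Within a tolerance of 0.1 read, 89.1% to 93.8% of these values were whole per library, against 20% by chance. The value of 1 read implied 17.6 to 19.3 megareads mapped per library, with a mean of 19 megareads in Sg-Con and 18.5 in Sg-C3. The offset and the value of 1 read were chosen to give the most whole values, so these depths are estimates.

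Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). Fold changes are Sg-C3 minus Sg-Con on that scale, which understates the change of genes with low FPKM. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called higher or lower. SE is limma's moderated standard error, SD is taken over the 3 libraries of a group, and fold is the ratio of the groups' mean FPKM. Values were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

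Before the data were examined, 33 gene lists were fixed, covering macrophage programs, technical signals and markers of the cell types that a sort can hold. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and limma's fry beside it. The genes named in the text follow a rule fixed at the same time. It takes 7 genes in every case (C3, C3ar1, C5ar1, Pik3cg, Cd274, Arg1 and Adgre1), the 12 highest and 12 lowest fold changes among called genes whose groups do not overlap, that reach a mean of 1 FPKM in a group and that carry no predicted name, and from each list the 4 tested members with the smallest p and any called member. The text gives examples of the called members. Fscn1, Col1a1 and Csf1r are named beside them as markers that did not pass, chosen after their values were seen, and other genes chosen that way are marked as such.

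The script was checked on 10 simulated sets of the 11198 tested genes with 200 genes changed. It found 75.3% of genes changed 2-fold and 96.2% of genes changed 4-fold, 4.3% of its calls were false, and 2 of 300 tests of unchanged lists passed. The simulated genes vary independently, which real genes do not. Alternatives fixed before the data were examined were another pseudocount (0.1), no filter, a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, array weights, a robust variance prior, the style of the sample titles as a covariate, an adjusted p threshold of 0.1 and leaving out each library. Further alternatives were chosen after seeing the data.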

Results

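Macrophages sorted from CT26 tumours on day 15 were profiled by RNA sequencing in 3 libraries from Sg-Con tumours and 3 from Sg-C3 tumours, to ask how macrophages differ when the tumour cells carry a guide against complement C3. The FPKM values of a library summed to between 474579 and 487358, and the values imply between 17.6 and 19.3 megareads mapped per library. Libraries of the same group correlated at Pearson r of 0.986 to 0.990 over log2 values of all genes, and libraries of different groups at 0.945 to 0.974. No 2 libraries were the same. The first principal component held 75.1% of the variance and separated the groups, and the second held 10.3%. Values with ± are means and SD of FPKM with n = 3 per group, and log2 fold changes are Sg-C3 minus Sg-Con.

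Macrophage samples sorted from Sg-C3 tumours held more RNA of most MHC class II genes and less of Arg1 and the scavenger receptor gene Cd163 than those from Sg-Con tumours. Of 8 tested dendritic cell markers 5 were higher as well, so these values do not place the change in the macrophages alone. H2-Aa, a chain of MHC class II, rose from 332 ± 245 to 3943 ± 529 FPKM (log2 fold change 3.98, SE 0.66, limma adjusted p = 0.00493), with a log2 fold change of 3.12 without Sg-Con replicate 2. Arg1, which breaks down arginine, fell from 327 ± 282 to 25.4 ± 17.9 FPKM (log2 fold change -3.64, SE 0.79, adjusted p = 0.0109), with log2 fold changes of -2.97 without Sg-Con replicate 2 and -2.85 without Sg-C3 replicate 2. Cd274, which encodes the checkpoint ligand PD-L1, rose from 70.5 ± 9.65 to 341 ± 50.3 FPKM (log2 fold change 2.26, SE 0.15, adjusted p = 7.80e-04). C3 itself was higher in the sorted samples, from 75.9 ± 15.3 to 173 ± 24.5 FPKM (log2 fold change 1.19, SE 0.17, adjusted p = 0.0032). Beside it, 7 of 13 tested fibroblast markers were higher and 2 lower. The genes of the receptors for complement fragments C5a and C3a fell, C5ar1 from 203 ± 11.3 to 112 ± 8 FPKM and C3ar1 from 128 ± 7.7 to 83.2 ± 14 FPKM (log2 fold changes -0.85 and -0.63, adjusted p = 0.00167 and 0.00918). Pik3cg, a PI3-kinase subunit gene of leukocytes, did not pass, at 11.1 ± 1.37 against 8.73 ± 0.748 FPKM (adjusted p = 0.0703). Adgre1, the gene of the macrophage marker F4/80, stood at 173 ± 11.6 and 172 ± 29.8 FPKM (adjusted p = 0.896).

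**Figure D1:**
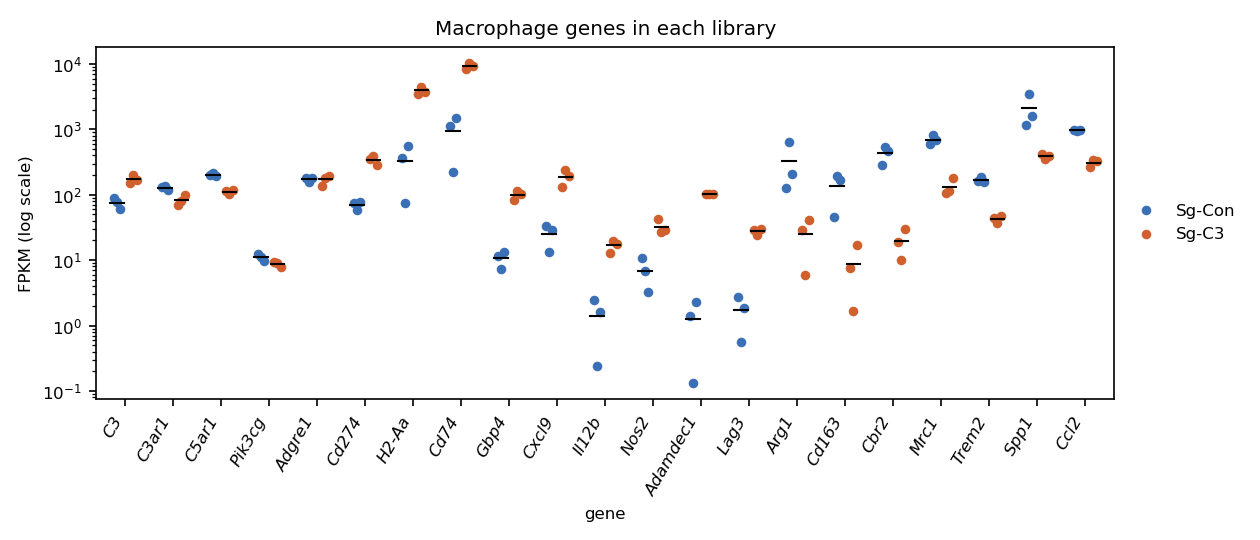
FPKM of 21 genes in the sorted macrophage samples, on a log axis. Each library has 1 point (Sg-Con blue, Sg-C3 orange), and a line marks the mean of the 3 libraries of a group. H2-Aa lay between 3499.84 and 4528.84 FPKM in Sg-C3 and between 74.88 and 561.44 in Sg-Con, while Adgre1 overlapped between the groups.

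The highest fold changes outside the MHC class II genes belonged to Adamdec1, a secreted protease gene, which rose 81.1-fold from 1.27 ± 1.07 to 103 ± 1.6 FPKM, Dnase1l3 (log2 fold change 4.18), Klra17 (4.16), Gpr31b (3.51), the inhibitory receptor gene Lag3 (3.48), the chemokine receptor gene Ccr7 (3.28) and the cytokine gene Il27 (3.25). The lowest beside Arg1 belonged to Cbr2, which fell from 431 ± 130 to 19.5 ± 9.77 FPKM (log2 fold change -4.47), the scavenger receptor gene Cd163 (-3.97), Lyve1 (-3.91), F13a1 (-3.65), Fcrls (-3.54), the keratin gene Krt8 (-3.44), Pmp22 (-3.08), Pf4 (-3.05), Fcna (-2.98), the folate receptor gene Folr2 (-2.94) and Slco2b1 (-2.94). Their adjusted p values ran from 7.80e-04 for Adamdec1 to 0.00779 for Cd163. Of 11198 genes tested with limma, 4972 were called, 1418 higher and 3554 lower in Sg-C3, and 509 and 409 of them had a log2 fold change of at least 1 or at most -1. The 3 values of a group lay wholly above or below the other group's for 57.6% of tested genes, where chance gives 10%.

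The excess of lower calls depended on the scaling. The median log2 fold change of all tested genes was -0.16, and 71.5% of calls were lower with the deposited scaling, against 56.9% after quantile normalization and 47.1% after median-ratio scaling. A relative median is the median of a list minus that shift. Without Sg-C3 replicate 1 or Sg-C3 replicate 2 the calls numbered 3293 and 2780. With both Sg-C3 replicate 1, which held the most neutrophil RNA, and Sg-C3 replicate 3, which held the most immediate early RNA, left out (chosen after seeing the data), 1 Sg-C3 library remained, so that all spread came from Sg-Con. There H2-Aa, H2-Eb1 and Cd74 had log2 fold changes of 4.18, 4.26 and 3.84 but were not called.

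Of the 33 lists, 30 had enough tested members, and 15 passed camera at the preset correlation, 13 up and 2 down. None passed with an estimated correlation, where the lowest adjusted p was 0.181, and 17 passed fry's directional test. Fry passed 13 of the 15, but not chemoattractants (0.18) or classical monocytes (0.0869), and it passed 4 lists that camera did not, alternative activation (0.0483), lipid-associated genes (0.0192), inhibitory ligands and receptors (0.0309) and carcinoma markers (0.00577). Camera at the preset correlation also passed between 10 and 19 lists in the 9 other splits of the 6 libraries into 3 and 3, where fry passed 0 and limma called 0 genes (at most 772 at an unadjusted p under 0.05). Each of these splits mixes the groups on both sides, which widens the spread and leaves part of the group difference. Their counts are therefore no measure of chance. Its calls are given below beside the counts of member genes. For 20 lists the counts of members called were the same adjusted over the list alone, and the other 13 are given where they occur.

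Most tested members of the antigen presentation and interferon lists were higher. In the MHC class II list, 10 of 12 tested members rose and 1 fell, with a relative median of 2.53. H2-Ab1 rose 11.8-fold, H2-Eb1 12.3-fold and Cd74, the invariant chain, from 948 ± 654 to 9304 ± 1038 FPKM, and Ciita, the master regulator of these genes, rose from 1.4 ± 1.04 to 8.85 ± 2.9 FPKM (log2 fold change 2.10, SE 0.37). H2-Ea-ps, named as a pseudogene, rose 11.9-fold. The single lower member was Ifi30, a lysosomal thiol reductase gene (log2 fold change -0.43, adjusted p = 0.0405), whose adjusted p was 0.0948 without Sg-Con replicate 1, 0.0659 without Sg-Con replicate 3, 0.115 without Sg-C3 replicate 1, 0.109 without Sg-C3 replicate 2 and 0.184 after median-ratio scaling. In the interferon gamma list 19 of 21 members rose and none fell (20 adjusted over the list alone), with a relative median of 1.79. Gbp4 rose 9.39-fold, the T cell chemoattractant Cxcl9 7.57-fold, Gbp2 4.09-fold and Irf1 1.87-fold. In the type I interferon list 22 of 25 rose and none fell, with a relative median of 1.32, among them Isg15 (log2 fold change 2.14), Rsad2 (2.16) and Irf7 (1.45). In the MHC class I list 13 of 18 rose and none fell (13 and 1 adjusted over the list alone), with a relative median of 1.01, and Tap1, H2-K1 and B2m had log2 fold changes of 1.49, 1.07 and 0.84. All 4 lists passed camera up, with adjusted p = 3.03e-07 for MHC class II, 4.13e-16 for interferon gamma, 1.08e-13 for type I interferon and 3.20e-09 for MHC class I, and each had adjusted p = 0.365 with an estimated correlation. Beside these groups, 11 of 13 measured NK and cytotoxic lymphocyte markers and 8 of 16 measured dendritic cell markers were higher when tested without a filter.

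Some inflammatory cytokine genes rose as well. In the classical inflammatory activation list 14 of 25 members rose, 1 fell and 10 did not pass. The relative median was 0.75, with camera adjusted p = 9.52e-08 (adjusted p = 0.181 with an estimated correlation). Il12b rose from 1.42 ± 1.1 to 16.8 ± 3.42 FPKM, Ccl5 6.18-fold, Nos2, the inducible nitric oxide synthase, 4.75-fold and Il6 4.6-fold, while Osm fell from 145 ± 7.04 to 76.2 ± 24.1 FPKM. In the costimulatory ligand list 6 of 11 rose and 2 fell, with camera adjusted p = 8.46e-04 (adjusted p = 0.365 with an estimated correlation), and Cd40 rose 7.48-fold and Cd86 2.04-fold while Tnfsf9 fell (log2 fold change -1.25). Without Sg-Con replicate 1 or Sg-C3 replicate 2, 1 costimulatory gene fell. Inhibitory ligands and receptors went both ways, 6 of 18 higher and 6 lower, with adjusted p = 0.134 with camera and 0.0309 with fry, and 3 were lower without Sg-C3 replicate 1 or Sg-C3 replicate 2. Pdcd1lg2, the gene of the ligand PD-L2, rose 13.3-fold from 0.587 ± 0.101 FPKM and Il10 from 370 ± 81 to 803 ± 132 FPKM, and Nt5e and Cd200r1 fell (log2 fold changes -2.63 and -1.53). Among the chemoattractants 8 of 16 rose and 5 fell (9 and 5 adjusted over the list alone). Ccl8 rose 4.93-fold, and the monocyte attractants Ccl2 and Ccl7 fell from 963 ± 20.7 to 309 ± 38.8 and from 889 ± 72.7 to 225 ± 69.7 FPKM. That list passed camera up at adjusted p = 0.0245 (adjusted p = 0.365 with an estimated correlation), but not fry (0.18), and not camera after quantile normalization (0.145) or median-ratio scaling (0.191), with a mean of at least 5 FPKM required (0.0539) or with library sums without the top 50 genes (0.0504). Beside these groups, 5 of 11 tested neutrophil markers were higher.

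In the alternative activation list 11 of 21 members fell and 5 rose, with a relative median of -0.85. The mannose receptor gene Mrc1 fell from 700 ± 119 to 134 ± 40 FPKM, Stab1 from 366 ± 95.8 to 61.5 ± 25.1 FPKM and Chil3 from 60.3 ± 35.2 to 7.16 ± 4.27 FPKM. Pdcd1lg2 and Il10 were among the members that rose, which numbered 3 without Sg-C3 replicate 2, and the list had adjusted p = 0.764 with camera and 0.0483 with fry. In the lipid-associated list 6 of 17 fell and none rose, among them Trem2 (log2 fold change -1.95), Spp1 (-2.28), which codes for osteopontin, and the lysosomal protease gene Ctsd (-1.47), with camera adjusted p = 0.148 (0.0402 without Sg-Con replicate 2 and 0.0444 after quantile normalization) and 0.0192 with fry. Of these lipid genes 1 rose without Sg-Con replicate 1, Sg-Con replicate 3 or Sg-C3 replicate 3. Phagocytic and scavenger receptors included 10 of 19 lower and 4 higher members (11 and 5 adjusted over the list alone), with camera adjusted p = 0.422. Mertk, a receptor for apoptotic cells, fell (log2 fold change -1.62), and Timd4, another, rose 12.7-fold. The Fc receptor gene Fcgr4 rose 4.46-fold. In the matrix remodelling and angiogenesis list 6 of 20 rose and 4 fell, with camera adjusted p = 0.112 (0.0428 without Sg-C3 replicate 1). The collagenase gene Mmp13 rose from 190 ± 108 to 1652 ± 420 FPKM, and Timp2, an inhibitor of such proteases, fell from 144 ± 6.14 to 50.9 ± 8.1 FPKM. Beside the matrix genes, 7 of 13 tested fibroblast markers were higher, Dcn 5.19-fold, and 2 were lower. Sg-Con replicate 2 had the highest values of Arg1 (649.77 FPKM), Cd163 (195.85) and Spp1 (3510.18) and the lowest of H2-Aa (74.88).

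**Figure D2:**
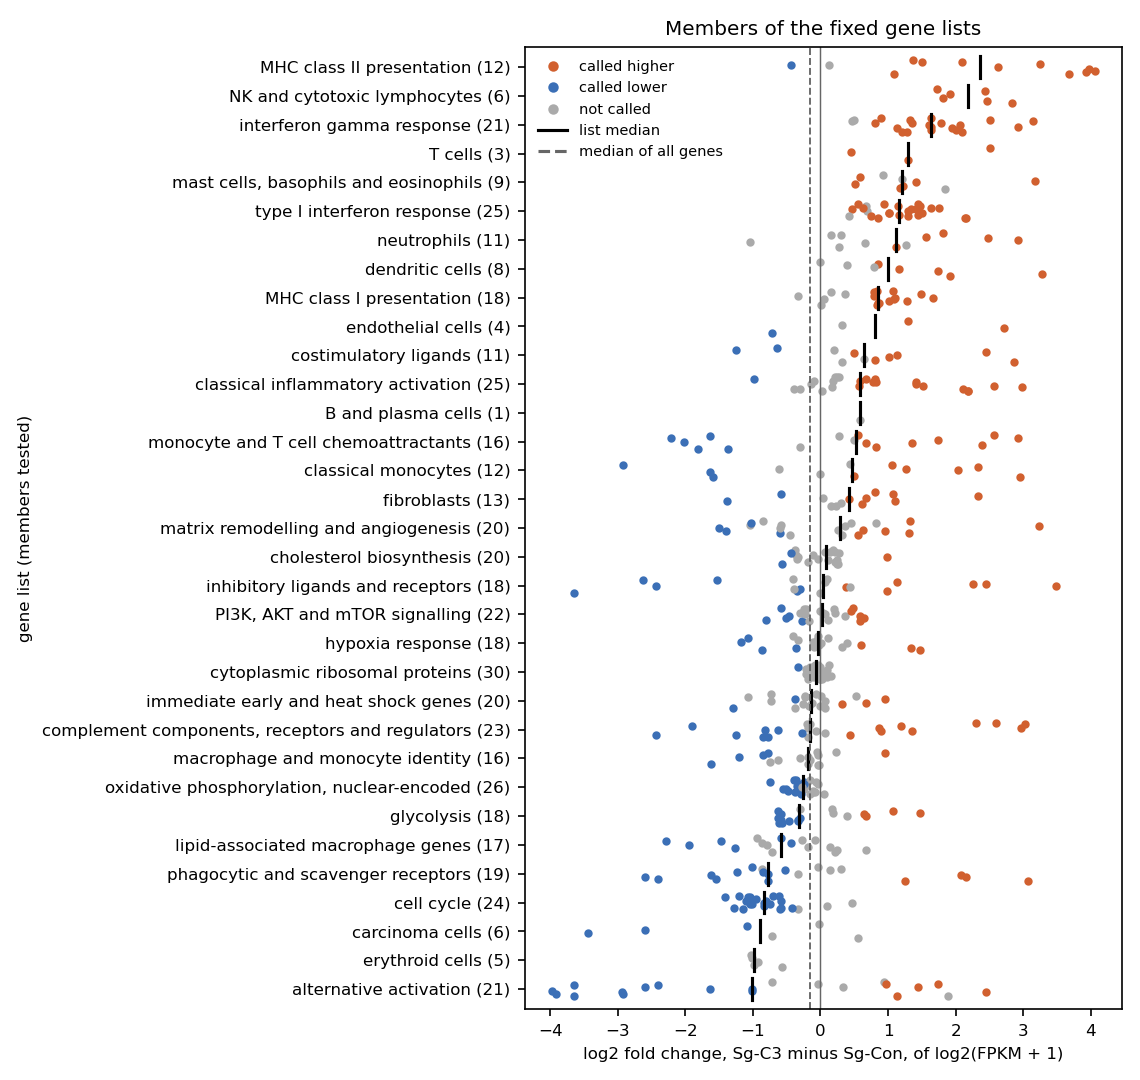
Log2 fold change of each tested member (points) of the 33 fixed gene lists, coloured by whether limma called it higher, lower or neither, with the list median (black line) and the median of all tested genes at -0.16 (dashed line). The MHC class II, NK and interferon gamma lists sit highest, with medians of 2.36, 2.18 and 1.63, and the alternative activation list sits lowest at -1.01.

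Complement and PI3-kinase genes changed in both directions. In the complement list 9 of 23 members rose and 8 fell, with camera adjusted p = 0.399 and a median of -0.15 that became 0.03 after median-ratio scaling. Beside C3, the factor B gene Cfb rose 4.73-fold and Itgax, a complement receptor subunit gene, rose from 27.9 ± 16.9 to 197 ± 18.9 FPKM, and C5ar1 and C3ar1 were among the members that fell. Beside this list 7 of 13 tested fibroblast markers were higher and 2 lower. In the PI3K, AKT and mTOR list 5 of 22 rose and 5 fell, among them Pik3cb (log2 fold change 0.58) and Pik3r2 (-0.81), with camera adjusted p = 0.322. After median-ratio scaling 7 rose and 1 fell, and without Sg-C3 replicate 1 or Sg-C3 replicate 2 only 2 rose and 2 fell (3 and 2 without Sg-Con replicate 1 or Sg-Con replicate 2). The complement, PI3K, inhibitory, hypoxia, immediate early and ribosomal lists were the 6 whose median, mean and camera direction differed in sign.

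Most cell cycle genes fell. Of 24 members, 21 fell and none rose, with a relative median of -0.67, and 17 still fell after median-ratio scaling. Ccna2, Plk1 and Rrm2 had log2 fold changes of -1.28, -1.14 and -1.07. The 3 that did not pass, named after their values were seen, were Mki67 (0.46), Pcna (0.09) and Aurka (-0.34). The list passed camera down at adjusted p = 2.68e-04 (adjusted p = 0.554 with an estimated correlation), and 3 carcinoma markers were lower beside it. Of 26 nuclear-encoded genes of oxidative phosphorylation 14 fell and none rose (17 lower adjusted over the list alone), with camera adjusted p = 0.0104 (adjusted p = 0.554 with an estimated correlation). Ndufs7 and Sdha had log2 fold changes of -0.75 and -0.56, but the relative median was only -0.10, and after median-ratio scaling 4 members fell and camera gave 0.191. Without Sg-C3 replicate 2, 4 members fell, without Sg-Con replicate 1, 5 fell, and without Sg-Con replicate 3 or Sg-C3 replicate 1, 8 fell. Among glycolysis genes 10 of 18 fell and 4 rose (11 and 5 adjusted over the list alone), with camera adjusted p = 0.843. Eno1 and Pgam1 fell (log2 fold changes -0.59 and -0.63), and Hk2, a hexokinase gene, rose 2.84-fold. In the hypoxia list 3 of 18 rose, including Ddit4 (log2 fold change 1.34), and 4 fell, including Bnip3 (-1.18), against 3 and 3 adjusted over the list alone, with camera adjusted p = 0.422 and a median of -0.04 that became 0.11 after median-ratio scaling. Without Sg-Con replicate 1, 3 hypoxia genes rose and 2 fell, and without Sg-Con replicate 2, 2 rose and 2 fell. Cholesterol biosynthesis had 1 higher member, Pmvk (log2 fold change 0.99), and 2 lower ones of 20 (1 and 0 adjusted over the list alone), with camera adjusted p = 0.287, and 0 were lower without Sg-Con replicate 2, Sg-Con replicate 3, Sg-C3 replicate 1 or Sg-C3 replicate 2. Of the technical lists, immediate early and heat shock genes had 3 of 20 members higher, Dnajb1 among them (log2 fold change 0.95), and 2 lower (1 and 0 adjusted over the list alone), with camera adjusted p = 0.449. Without Sg-C3 replicate 3, 9 of them were lower, and without Sg-Con replicate 1, Sg-Con replicate 2 or Sg-C3 replicate 1, 1 was higher and 0 lower. Ribosomal proteins had 1 of 30 lower and none higher (0 and 0 adjusted over the list alone), or 3 lower without Sg-C3 replicate 1, with camera adjusted p = 0.744, but after median-ratio scaling 4 were higher and none lower and the list passed camera up at 0.0228.

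Markers of other cell types moved with the groups. Without a filter, 11 of 13 measured NK and cytotoxic markers rose and none fell, with camera adjusted p = 8.29e-11. The filter left 6, all higher, with camera adjusted p = 1.54e-07 (adjusted p = 0.181 with an estimated correlation), but most of these were near 0 in Sg-Con and reached it only through their Sg-C3 values. The granzyme genes Gzma and Gzmb rose from 0.203 ± 0.0874 to 7.77 ± 2.16 FPKM and from 0.227 ± 0.159 to 5.94 ± 2.6 FPKM, and the receptor gene Klrk1 rose 7.81-fold. Of 16 measured T cell markers 9 rose and none fell without a filter, including Cd3g, which reached 1.57 ± 0.47 FPKM, and Cd4 (8.24-fold). Cd3e, chosen after its values were seen, overlapped between the groups. The filter left 3 of the T cell markers, and only 1 NK marker and 1 T cell marker with any Sg-C3 library left out. Too few T cell, B cell and endothelial markers passed the filter for camera. Of 11 neutrophil markers 5 rose and none fell, with camera adjusted p = 4.20e-04 (adjusted p = 0.365 with an estimated correlation). Without Sg-C3 replicate 1, 3 rose and 1 fell, and 3 rose without Sg-Con replicate 1 or Sg-Con replicate 2. S100a9 ranged from 189.28 to 734.3 FPKM in Sg-C3 with the highest value in replicate 1, and Csf3r rose 2.22-fold. Of 8 dendritic cell markers past the filter 5 rose and none fell (6 higher adjusted over the list alone), with camera adjusted p = 1.94e-04 (adjusted p = 0.365 with an estimated correlation). Without a filter, 8 of 16 rose and none fell, with camera adjusted p = 1.05e-05. Batf3 rose from 1.61 ± 1.42 to 7.88 ± 1.77 FPKM, and Fscn1 stood at 7.59 ± 1.11 and 7.62 ± 1.16. Of 9 mast cell, basophil and eosinophil markers 6 rose and none fell (9 higher adjusted over the list alone), with camera adjusted p = 5.57e-06 (adjusted p = 0.365 with an estimated correlation), including Hdc (9.31-fold) and Kit (5.27-fold), and 1 of 5 rose without Sg-C3 replicate 1 or Sg-C3 replicate 2. Without a filter, 8 of 14 rose and none fell. Of 13 fibroblast markers 7 rose and 2 fell, with camera adjusted p = 5.78e-04 (adjusted p = 0.405 with an estimated correlation). With a mean of at least 5 FPKM required, 3 of 7 rose and 2 fell and camera gave 0.114, and 1 fell without Sg-Con replicate 2 or Sg-C3 replicate 1. Dcn rose 5.19-fold, Thy1 and Col1a2 fell (log2 fold changes -1.38 and -0.59), and Col1a1 stood at 4.97 ± 0.821 and 5.69 ± 1.24 FPKM.

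Of 6 carcinoma markers 3 fell and none rose (4 and 1 adjusted over the list alone), with adjusted p = 0.322 with camera and 0.00577 with fry, and 1 rose without Sg-Con replicate 2 or Sg-C3 replicate 1. Krt8 fell from 14.3 ± 6.73 to 0.323 ± 0.0551 FPKM, Krt20 from 22.1 ± 10.6 to 3.27 ± 2.57 FPKM and Cdh1 from 3.54 ± 1.2 to 1.09 ± 0.208 FPKM. Of 4 endothelial markers 2 rose, including Pecam1 (6.81-fold), and 1, Cdh5, fell. With an Sg-Con library left out Cdh5 no longer reached the filter, and with an Sg-C3 library left out or after median-ratio scaling 0 fell. Only 1 rose without Sg-C3 replicate 2. The only B cell marker tested, Cd79b, did not pass, at 2.92 ± 1.62 and 4.56 ± 1.29 FPKM. None of 5 erythroid genes passed, with camera adjusted p = 0.399, and 4 were lower without Sg-C3 replicate 1. Of 16 macrophage and monocyte identity genes 4 fell and 1 rose, with camera adjusted p = 0.449. Lyz2 fell from 7712 ± 915 to 3378 ± 579 FPKM and Cd68 from 725 ± 32.3 to 403 ± 38.5 FPKM, Aif1 rose 1.88-fold, and Csf1r stood at 402 ± 43.7 and 324 ± 41 FPKM (adjusted p = 0.0791). Of 12 classical monocyte markers 6 rose, among them Plac8 (7.58-fold) and Ly6c2 (4.34-fold), and 3 fell, among them the receptor gene Ccr2 (log2 fold change -1.59). Camera gave adjusted p = 0.0382 for that list (adjusted p = 0.423 with an estimated correlation), fry gave 0.0869, and camera gave 0.145 without Sg-Con replicate 1, 0.127 after quantile normalization, 0.191 after median-ratio scaling, 0.0641 without a filter, 0.0539 with a mean of at least 5 FPKM required and 0.0641 with library sums without the top 50 genes.

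**Figure D3:**
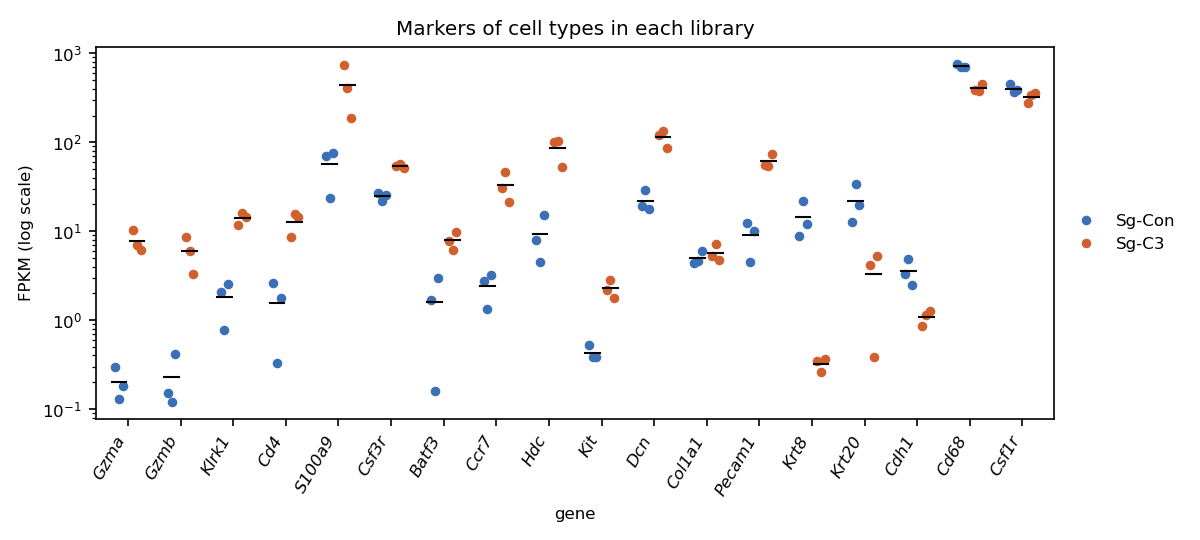
FPKM of 18 cell type markers on a log axis, with 1 point per library (Sg-Con blue, Sg-C3 orange) and a line at the mean of the 3 libraries of a group. Gzma lay between 6.08 and 10.2 FPKM in Sg-C3 and between 0.13 and 0.3 in Sg-Con, and Krt8 went the other way, at no more than 0.36 in Sg-C3 and at least 8.92 in Sg-Con.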

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

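The genes named here were picked by their values after the results were seen and did not reach the filter. Among the 4289 genes that stayed below the filter, 4 were listed at 0 in every Sg-Con library and at no less than 0.5 FPKM in every Sg-C3 library. The main comparison did not use these values. One of them is Ifng, the gene of interferon gamma and a member of the NK and cytotoxic lymphocyte list. It stood at 1.62, 1.15 and 0.85 FPKM in Sg-C3 replicates 1 to 3. The others are Gm5416 (3.93, 3.63 and 0.82 FPKM) and the microRNA genes Mir6418 (2.14, 0.66 and 1.34) and Mir674 (0.88, 2.45 and 0.83). At the depth implied here, such values can rest on a few reads, above all in short genes such as the microRNA genes. None of the 4 was tested in the main comparison, while the setting without a filter took in all 15487 genes. No gene below the filter showed the opposite, 0 in every Sg-C3 library and at least 0.5 FPKM in every Sg-Con library (count 0).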

How the results depend on the processing

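The alternatives named under the processing were fixed before the data were examined, and 2 were chosen after seeing the data (both Sg-C3 replicates 1 and 3 left out, and library sums without the top 50 genes). Tests made for counts were not run, since the table holds FPKM. No paired analysis was possible because the groups share no replicate labels. Calls numbered between 3684 (mean of at least 5 FPKM, fewer genes tested) and 6224 (threshold of 0.1) under the settings that kept all libraries, and called genes shared with the main list never had the opposite direction. Leaving out 1 library gave 2780 to 5062 calls, 810 to 1423 higher and 1970 to 3639 lower, 385 to 560 higher by at least 1 and 324 to 581 lower by at least 1, with fewer samples as one cause, and 14 to 16 lists. Median-ratio scaling, which centres the genes, gave 2211 higher and 1969 lower, with 263 at -1 or less. A pseudocount of 0.1, which widens the fold changes of low genes, gave 700 at -1 or less. With both Sg-C3 replicates 1 and 3 left out, 2463 genes were called, 611 higher and 1852 lower, and 610 at -1 or less (1 Sg-C3 library left, so all spread comes from Sg-Con). Camera with an estimated correlation passed 0 lists. Of 1885 pairs of a named gene and a setting, 1847 kept direction and side of the threshold, 25 lost the call (Ifi30, and 16 with both replicates left out, among them H2-Aa at 4.18 with adjusted p = 0.0527, H2-Eb1 at 4.26 with 0.0559, Cd74 at 3.84 with 0.0586, Itgax at 3.13 with 0.0572 and Nos2 at 1.95 with 0.0575), 3 gained it (all Fos) and 10 changed sign. The sign changes were in Adgre1 (0.17 with median-ratio scaling, 0.03 without the top 50 genes, 0.08 with both replicates left out, -0.12 to 0.13 without 1 library) and Fscn1 (-0.01 with array weights, -0.14 with both left out, -0.10 to 0.10 without 1 library), neither called in any setting; the cause was not tested. At this depth, genes of low FPKM rest on few reads.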

Other observations

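The term search and the tests of explanations given here were chosen after the results were seen, except the split count of gene lists. Gene groups beyond the fixed lists were searched with the GO biological process terms of the table, with 697 terms of 10 to 300 genes tested by Fisher's exact test against 6996 tested and annotated genes. Of these, 51 terms were enriched among the 340 annotated genes higher by a log2 fold change of at least 1, and 4 among the 289 lower ones. The term for response to protozoan held 16 higher genes of 23 (1.12 expected, adjusted p = 4.11e-14), mostly guanylate-binding proteins and immunity-related GTPases that attack intracellular parasites, such as Gbp9 (log2 fold change 1.46). The term for MHC class I presentation of endogenous peptides through the ER held 6 higher genes of 11 (adjusted p = 1.83e-04), all H2-Q genes such as H2-Q6 (109 ± 15.3 to 219 ± 22.4 FPKM), which are near-identical and can share reads. Angiogenesis was enriched in both directions, with 14 higher genes of 100 (adjusted p = 0.00717) and 16 lower ones (adjusted p = 0.00193).

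Several called genes that no list held, chosen after their values were seen, also moved. The heme oxygenase gene Hmox1 fell from 562 ± 291 to 175 ± 5.21 FPKM, the transcription factor gene Maf from 52.4 ± 13 to 16.2 ± 5.33, Nrp1 from 46.8 ± 11.4 to 13.3 ± 4.49, Gas6, whose product bridges apoptotic cells to phagocytes, from 94.1 ± 25 to 19.3 ± 5.19, and the glucocorticoid-responsive gene Fkbp5 from 52 ± 16.4 to 9.26 ± 4.38. Il1rn, which encodes an antagonist of the interleukin-1 receptor, rose 2.35-fold. Fos, a member of the immediate early list, did not pass (adjusted p = 0.116, but 0.00324 without Sg-C3 replicate 3), with 669.54 FPKM in Sg-C3 replicate 3 against 204.6 and 158.89 in the other Sg-C3 libraries.

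The gene count was as large in 1 of 10 splits of the 6 libraries, the real one, with 4972 genes against at most 0 in the others, and the list count in 3 of 10, with 15 lists against up to 19. Splits of 3 and 3 are too few for a share under 0.05, and all the others mix the groups on both sides. The group difference then counts as spread, so few gene calls there were set by the design. These counts do not speak to chance.

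Most calls were lower in Sg-C3, where abundant genes such as those of MHC class II took a larger share of the FPKM sum. The 50 genes of the highest mean FPKM do not account for all of the excess of lower calls. With library sums taken without these top 50 genes, the median log2 fold change of tested genes stayed at -0.11, and at -0.14 to -0.10 with any library left out. A larger share taken by genes outside the top 50 was not tested. Whether the deposited scaling is the cause cannot be told apart from a wider fall in RNA, since median-ratio scaling centres the genes and so evens out the directions, with 47.1% of calls lower, and ribosomal proteins, with a median of -0.06, did not share the shift of -0.16. The biological difference between the tumours stays open as an explanation.

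NK and T cell transcripts were higher in Sg-C3. A lower share of macrophage RNA, with the mix of other cells unchanged, would raise markers of every other cell type. It does not account for 3 carcinoma markers, which fell with log2 fold changes of -1 or less. The mix of other cells can differ between the tumours too, so these 3 markers cannot decide whether the macrophage share was lower. RNA of lymphocytes that passed the sort may explain part of the rise in NK and T cell transcripts. Of the 29 measured T cell and NK genes, 21 had all Sg-C3 values above all Sg-Con values. Cd3e did not, at 0.84, 0.78 and 1.58 FPKM against 2.2, 0.84 and 0.52. It is a T cell marker and does not bear on the NK markers, of which 11 of 13 rose and none fell without a filter. Macrophages can express some of the T cell and NK genes, so the source of these transcripts cannot be told apart. A sort on macrophage markers would be meant to remove lymphocytes.

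MHC class II genes were higher in Sg-C3. The low values of Sg-Con replicate 2 do not account for it, since the list median was 1.93 without that library and 2.36 with it. Dendritic cells in the sort may contribute, as 5 of the 8 tested members of their list rose, and 8 of 16 without a filter, with mean FPKM going from 0.0667 to 1.08 for Clec9a, 0.18 to 1.06 for Dpp4 and 0.267 to 0.767 for Ccr9. Of those 5, Ccr7, Batf3 and Xcr1 had log2 fold changes of 3.28, 1.92 and 1.16, and none of the 8 was called lower. Bst2 is also an interferon gene, Ccl22 is in 2 other lists, Flt3 stayed at no more than 0.33 FPKM and Zbtb46 at no more than 0.9, and Fscn1 did not differ past the threshold, so dendritic cells and a change in the macrophages cannot be told apart. The biological difference between the tumours stays open here too.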
